A study of Brachylophosaurus canadensis and Tyrannosaurus rex with 12 samples.

How the data were processed

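The samples were osteocytes and blood vessels of 2 fossil specimens, 1 Brachylophosaurus and 1 Tyrannosaurus. Per the labels, cortical bone was demineralised in 0.5 M EDTA at pH 8.0, the residue was passed through a 40 µm strainer, cells were collected from the filtrate and vessels from the strainer, and iron was removed with 5 mM pyridoxal isonicotinoyl hydrazone in 50 mM NaOH. The DNA preparation followed a protocol written for Omni-C, a proximity ligation method. Per the labels the library protocol was that of the KAPA HyperPlus kit for all 12 samples, while the titles name SRSLY for 8 of them, so the kit of those 8 rests on the titles alone. No extraction blanks, library blanks or samples of present-day tissue are part of the series, so no background could be subtracted.

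The authors deposited 1 list of aligned intervals per library. The submitters' processing notes name fastp, bedtools and the chicken build galGal6, without versions, roles or order. The aligner, the trimming settings and any filter on mapping quality are not given in the sources used here. Each deposited line gave a chromosome, a start, an end, a strand, the aligned sequence and a field of 0 or 1 whose meaning is not stated. The score column as deposited was 0 on every line, so no mapping quality was kept, and an interval that could have aligned to many places could not be told from a unique one. The other deposited columns hold coordinates and text and were not normalised, and repeated coordinates were kept in the lists. Alignments with gaps appear as several adjacent intervals, so an interval is an aligned block and not always a whole read. Read totals before alignment, and reads that did not align, were not used here, so no share of all reads could be computed.

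Intervals with the same chromosome, start, end and strand were counted once (distinct intervals), since libraries made by amplification hold copies. Distinct intervals per library were 315485, 285570 and 64802 for Brachylophosaurus osteocytes (KAPA, SRSLY and SRSLY_S, which are replicates 1, 2 and 3), and 345527, 80786 and 17732 for Brachylophosaurus vessels. They were 23341, 383299 and 31129 for Tyrannosaurus osteocytes, and 13764, 948672 and 22219 for Tyrannosaurus vessels. A share of 1 library therefore has a counting floor (3 intervals of its total) between 0.000316% and 0.0218%. Replicate numbers follow the order of the samples, which puts the library types in the same order in every group. Matched tests used the specimen, tissue and library type in the titles.

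Windows of 100 kb were used because neither the genome sequence nor an annotation of this build was used here, a substitution written down before the data were examined, together with the tests, the comparisons and the rule for named regions. Only the 34 assembled chromosomes entered the windows (10514 of 100 kb, 104971 of 10 kb), and lengths were taken from the highest coordinate seen. Counts were scaled to 1000000 distinct intervals per library (RPM), and windows with a mean of at least 144.5 RPM (10 intervals in the library of median depth) were tested as log2 of RPM plus 14.45 (1 such interval). limma 3.58.1 in R 4.3.3 fitted specimen, tissue and library type to all 12 libraries (lmFit, eBayes with a mean trend), and Benjamini-Hochberg adjusted p-values under 0.05 counted as differences. KAPA was set against the mean of SRSLY and SRSLY_S. For each comparison the 12 largest increases and the 12 largest decreases were named among windows past the threshold with the same sign in every matched pair, and the 10 densest windows of 10 kb were named as well. Only the comparison of kits had such windows. The limma fits were tested on simulated data with 100 windows changed 2-fold and 100 changed 4-fold. They recovered 28% to 53% of the former and 74% to 99% of the latter, with 2% to 3.77% of calls false. The simulated libraries had equal dispersion, a set value that was not estimated from the real libraries. Unequal dispersion was not simulated, so the rates for the real libraries are not known.

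Sequence classes were assigned per interval of at least 20 bases. An interval was a tandem repeat of a given unit length, up to 6 bases, when at least a share of 0.8 of its bases equalled the base 1 unit further on, and shorter intervals were counted as having no tandem repeat. Low complexity meant a tandem repeat or a triplet score (pairs of equal base triplets per triplet) above 2, and all other intervals were called non-repetitive. Coordinates seen with several sequences took the commonest one. Of 14 measures per library, 7 were treated as planned, among them the low-complexity share where the plan had named a share in repeats. The other 7 (the sequence classes, long non-repetitive intervals and the chromosome 16 stretch) were added after. Each of the 14 measures was compared by exact permutation tests, two-sided. Sign flips of 6 matched pairs were used for specimens and tissues (smallest p 0.0312). For kits there were 81 assignments of the KAPA label (smallest p 0.0123), and for the suffix sign flips of 4 pairs (smallest p 0.125). Adjusted p-values are over the 14 measures of a comparison. Similarity was the mean Spearman correlation within minus between labels, with the label permuted within matched sets, one-sided. Shares of single libraries carry Wilson 95% intervals. Python 3.11.15 was used with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Numba 0.67.0, statsmodels 0.14.6 and Matplotlib 3.10.9.

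The alternatives tried were every interval as deposited, a smaller and a larger pseudocount, no minimum density, library weights, no covariates, median ratio scaling, 1 Mb windows, no thinning, leaving out the densest 1% of windows, and leaving out each library in turn. Added after seeing the data were non-repetitive intervals only, leaving out the 4 libraries with under 25000 distinct intervals, whole chromosomes as the unit, and similarity among pairs of the same library type only. Left out were a filter at a mapping score of 30, counts over exons, and gene lists with their set tests, since the score is 0 throughout and no annotation was used here. Also left out were the planned exonic and coding shares, the share in repeats, and the purine share just upstream of interval ends. Gene lists were therefore not analysed here. Mitochondrial intervals were only counted, and their sequences were not examined. Intervals on unplaced scaffolds were counted and entered the sequence classes but no window.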

Results

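The series asked which DNA sequences could be read from osteocytes (bone cells) and blood vessels freed from the cortical bone of 2 non-avian dinosaurs, a Brachylophosaurus (a duck-billed dinosaur) and a Tyrannosaurus. Each of the 4 combinations of specimen and tissue had 3 libraries, named KAPA, SRSLY and SRSLY_S in the labels, and these are replicates 1, 2 and 3 of a group. KAPA is a kit that fragments and ligates double-stranded DNA, and SRSLY is a kit that ligates adapters to single-stranded DNA. The labels do not explain the suffix S. The 3 libraries of a group come from 1 specimen and differ in library type, so they are not separate animals, and every p-value measures only the spread between these libraries.

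The deposited values were genomic intervals where sequence aligned to the chicken genome (build galGal6), a living relative of dinosaurs. The 12 libraries held between 20044 intervals (Brachylophosaurus vessels SRSLY_S) and 1869209 intervals (Tyrannosaurus vessels SRSLY). After repeated coordinates were counted once, they held 13764 (Tyrannosaurus vessels KAPA) to 948672 distinct intervals (Tyrannosaurus vessels SRSLY). The median interval was 37 to 40 bases long in every library. The longest was 150 bases in every KAPA library and 151 bases in every SRSLY and SRSLY_S library. No annotation of this build was used here, so regions are given by position without gene names.

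Most distinct intervals carried simple sequence in every library. Low-complexity sequence made up 69.0% of the distinct intervals in the Brachylophosaurus osteocytes SRSLY library (Wilson 95% interval 68.8% to 69.2%) and 96.2% in the Tyrannosaurus vessels KAPA library (95.9% to 96.5%), the lowest and highest of the 12. These confidence intervals cover counting error only. Runs of C or G accounted for 28.9% ± 13.7 (SD, n = 12) and runs of A or T for 24.3% ± 9.47 of the distinct intervals. The AATGG repeat, a tandem repeat of a 5-base unit, made up 3.03% ± 1.68 of them, and the AT repeat 1.34% ± 2.52. Intervals with no tandem repeat made up 31.3% ± 9.37.

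**Figure D1:**
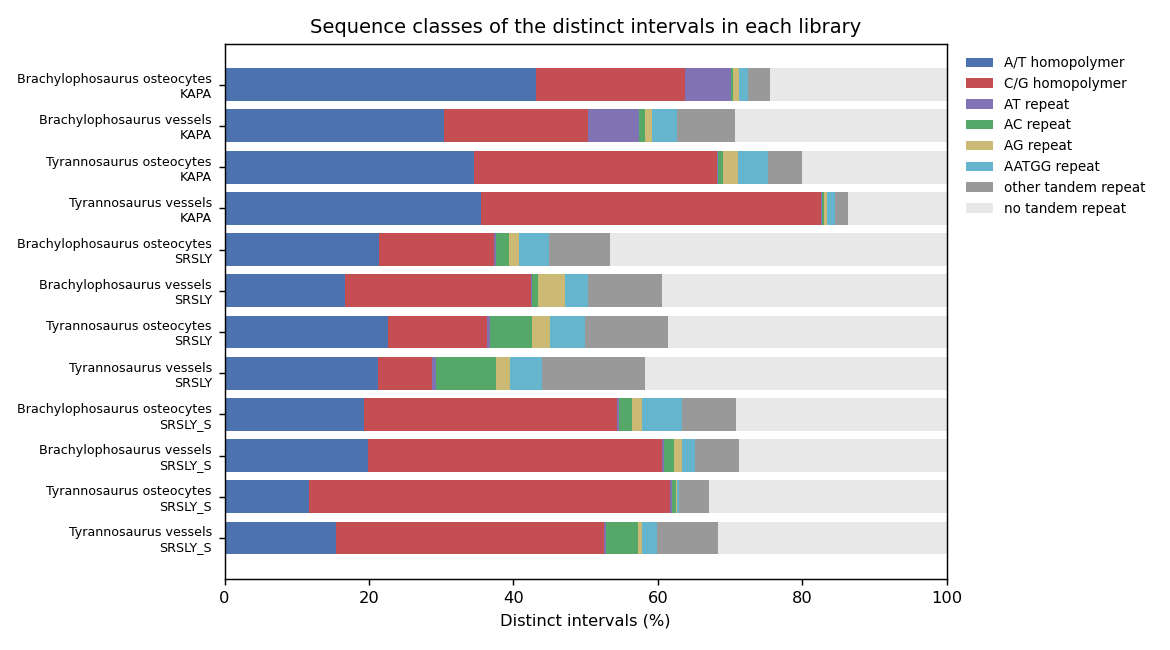
Share of the distinct intervals (%, horizontal axis) in each sequence class, as 1 stacked bar per library, for the 12 libraries ordered by library type. Intervals with no tandem repeat averaged 41.6% in the 4 SRSLY libraries, 30.6% in the 4 SRSLY_S libraries and 21.9% in the 4 KAPA libraries.

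The intervals were spread unevenly over the chromosomes. Chromosome 30 held 33.04 ± 21.4 times (SD, n = 12) as many distinct intervals as its share of the assembled length, chromosome 16 held 10.2 ± 4.96 times and chromosome 31 held 7.61 ± 6.12 times as many. Each of these ratios was above 1 in 12 of 12 libraries, as were those of chromosomes 25 (3.91 ± 1.43), 32 (2.51 ± 0.824) and 33 (2.38 ± 0.668). Chromosome W had a ratio of 0.420 ± 0.125. With non-repetitive intervals only, the ratio was 52.4 ± 24.96 for chromosome 16 and 14.5 ± 15.7 for chromosome 30. The densest 10 kb window lay on chromosome 30 from 10001 to 20000, with 42688 ± 33944 RPM (distinct intervals scaled to 1000000 per library), of which 68.9% were runs of C or G, while the whole of chromosome 30 held a mean of 5.70% of the intervals on assembled chromosomes. Such runs also led in the next 3 windows, on chromosome 31 from 1050001 to 1060000 and from 1040001 to 1050000 and on chromosome 2 from 116390001 to 116400000. The AATGG repeat led on chromosome 1 from 196440001 to 196450000, where it made up 72.3% of the intervals.

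**Figure D2:**
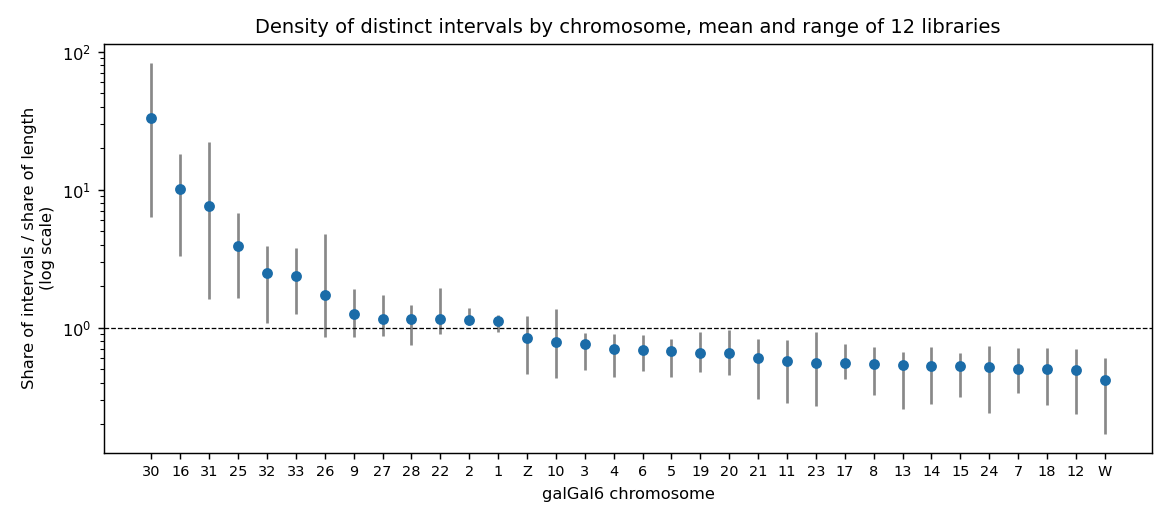
Share of the distinct intervals over share of the assembled length (vertical axis, log scale, no unit) for the 34 assembled chromosomes. Points are means and lines run from the lowest to the highest of 12 libraries, and chromosome 30 had the highest mean, 33.04.

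A stretch of chromosome 16 from 1790001 to 1850000 differed from the other dense regions, since its intervals were not repetitive. In its densest 10 kb window, from 1840001 to 1850000, 1.55% of the intervals were of low complexity and the density was 10616 ± 6751 RPM (SD, n = 12). The stretch held 13.9% ± 6.69 of all non-repetitive intervals, from 5.24% in the Tyrannosaurus osteocytes SRSLY_S library (Wilson 95% interval 4.35% to 6.32%) to 30.7% in the Tyrannosaurus osteocytes KAPA library (28.8% to 32.7%). Its density of such intervals was 917 to 5375 times that of the assembled chromosomes. Chromosome 16 carries the ribosomal RNA gene cluster of the chicken. Of the 6462 intervals on assembled chromosomes that held the binding site of any of 4 universal 18S ribosomal RNA primers, 6306 (97.6%) lay in this stretch. All 12 libraries had such intervals, and unplaced scaffolds were not searched. The stretch was singled out after its density was seen.

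**Figure D3:**
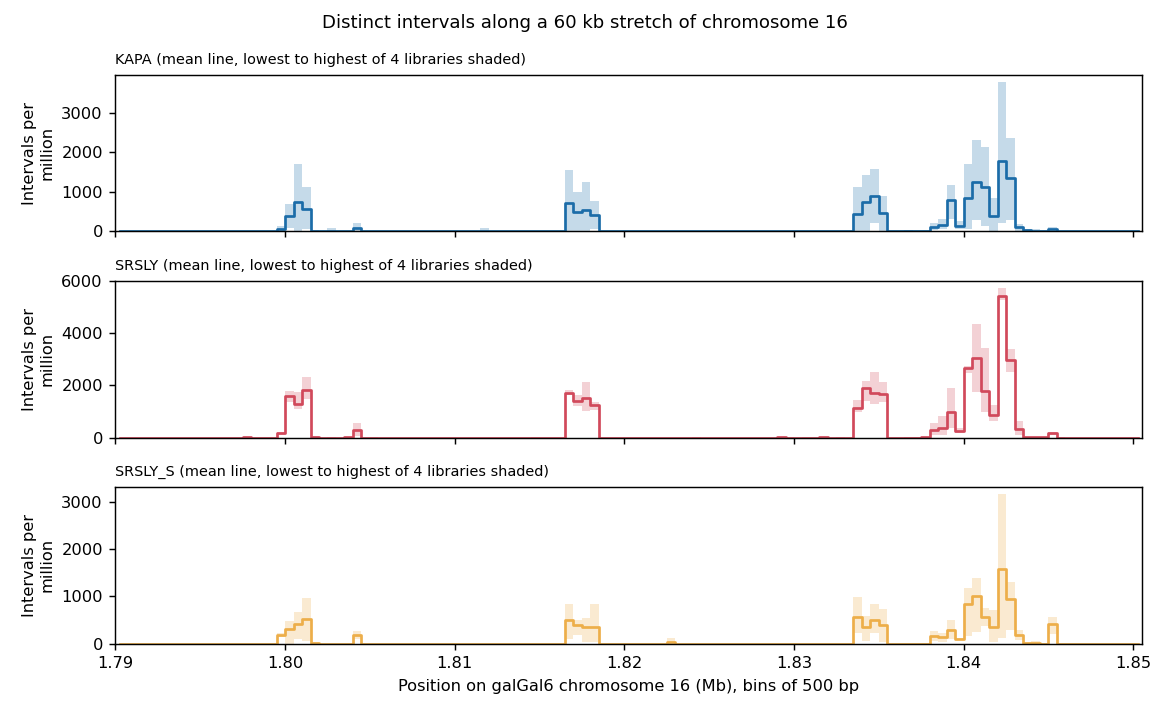
Density of distinct intervals (RPM, vertical axis) in bins of 500 bp along chromosome 16 (horizontal axis, Mb), with 1 panel per library type, each on its own vertical scale. Lines are means and shading runs from the lowest to the highest of 4 libraries, and signal appears in each of the 3 panels.

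The comparison of KAPA with both SRSLY library types asked whether the recovered sequences differed between kits. The longest interval was 150 bases in every KAPA library and 151 in every other library. Kit therefore cannot be told apart from any difference in how these libraries were sequenced or trimmed. Intervals in runs of A or T made up 35.9% ± 5.36 of the distinct intervals in KAPA libraries (SD, n = 4) and 18.5% ± 3.69 in SRSLY and SRSLY_S libraries (n = 8). KAPA was higher in 4 of 4 specimen and tissue combinations, by 17.4 ± 4.43 points (exact permutation test, two-sided, p = 0.0123, the smallest it can give, adjusted p = 0.0864 over 14 measures). This direction turned to -0.962 points (exact permutation p = 0.654) when every deposited interval was counted. Repeated coordinates made up 71.3% ± 2.81 of the intervals in KAPA libraries and 28.3% ± 12.6 in the others, again higher in 4 of 4 (exact permutation p = 0.0123, adjusted p = 0.0864). The shares of runs of C or G did not differ past the spread, with 30.3% ± 12.8 against 28.3% ± 14.9 (exact permutation p = 0.84), but the latter pools SRSLY at 15.7% and SRSLY_S at 40.8%. KAPA was above SRSLY in 3 of 4 combinations and below SRSLY_S in 3 of 4, and its difference from their mean was -9.11 points in Brachylophosaurus and 13.2 in Tyrannosaurus.

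Of 1021 windows of 100 kb, 261 (25.6%) differed between KAPA and SRSLY at an adjusted p under 0.05 in limma. KAPA was higher in 135 and lower in 126 (91 and 392 when every deposited interval was counted, 38 and 9 without the 4 shallowest libraries), and 244 of them had the same sign in all 4 combinations. Runs of A or T were the leading class in 78 of the 135 windows that were higher in KAPA (57.8%) and in 9 of the 126 that were lower (7.14%). In turn, runs of C or G led in 77 of the lower windows (61.1%) and in 46 of the higher ones (34.1%). Sequence with no tandem repeat, which includes intervals of low complexity by the triplet score, led in 31 of the lower and 5 of the higher windows. Among the 760 windows that did not pass, runs of A or T led in 29.7% and runs of C or G in 26.6%. These counts by class were made after the calls were seen and carry no test.

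The largest increase in KAPA was on chromosome 5 from 57.4 to 57.5 Mb, where 93.8% of the intervals were AT repeats (log2 fold change 4.79 ± 1.07, SE, limma adjusted p = 0.00931). The Brachylophosaurus KAPA libraries carried this increase, with 8229 and 9939 RPM (2417 and 3233 intervals), while the Tyrannosaurus KAPA libraries had 94.4 and 83.1 RPM (2 intervals and 1 interval). On chromosome 1 from 17.1 to 17.2 Mb, 90.5% were runs of A or T (log2 fold change 3.72 ± 0.39, limma adjusted p = 4.68e-05). Runs of A or T also led on chromosome 3 from 56.9 to 57 Mb (3.32), chromosome 2 from 116.6 to 116.7 Mb (3.29) and 113.2 to 113.3 Mb (3.00), chromosome 14 from 13.1 to 13.2 Mb (3.27), chromosome 1 from 8.1 to 8.2 Mb (3.22) and chromosome 9 from 18.7 to 18.8 Mb (2.93). AT repeats led on chromosome 1 from 31.3 to 31.4 Mb (2.91). The other 3 named increases were led by runs of C or G, on chromosome 4 from 67.4 to 67.5 Mb (3.32) and chromosome 3 from 20.8 to 20.9 Mb (2.97) and from 88.2 to 88.3 Mb (2.97). In each of the 12 named decreases the Tyrannosaurus KAPA libraries held 0 to 2 intervals, so the size of these log2 fold changes depends on the pseudocount and is no bound. The largest decrease in KAPA was on chromosome 31 from 6.1 to 6.2 Mb (log2 fold change -6.21 ± 0.62, limma adjusted p = 3.2e-05), where 49.5% of the intervals had no tandem repeat and 39.8% were runs of C or G. Chromosome 1 from 182.2 to 182.3 Mb (-5.60), chromosome 2 from 70.8 to 70.9 Mb (-4.57) and chromosome 31 from 5.8 to 5.9 Mb (-4.56) were also led by sequence with no tandem repeat. Most of that sequence was still of low complexity by the triplet score. Non-repetitive intervals made up 17.1% of the window on chromosome 31 from 6.1 to 6.2 Mb. In the other windows led by this class they made up 19.3%, 11.7% and 15.1%, in the order given. Runs of C or G led the decreases on chromosome 2 from 69.9 to 70 Mb (-4.98) and from 59 to 59.1 Mb (-3.29), chromosome 16 from 0.7 to 0.8 Mb (-4.06), chromosome 1 from 10.1 to 10.2 Mb (-3.93), chromosome 4 from 27.8 to 27.9 Mb (-3.62), chromosome 9 from 0.9 to 1 Mb (-3.61) and chromosome 8 from 19.6 to 19.7 Mb (-3.37). Chromosome 8 from 14.7 to 14.8 Mb (-3.52) was led by runs of A or T. The count of windows was 100 without the Tyrannosaurus vessels KAPA library, 140 without the Tyrannosaurus osteocytes KAPA library, 149 without the Tyrannosaurus osteocytes SRSLY library and 483 when every deposited interval was counted. It was 47 without the 4 shallowest libraries, where KAPA was left with its Brachylophosaurus libraries alone and 10 of the 24 named windows lost their call, 3 were no longer tested and the log2 fold changes ranged from -5.23 to -1.02 for the 12 decreases and from 1.74 to 7.39 for the 9 increases still tested. Of the named increases, those on chromosome 4 at 67.4 Mb (log2 fold changes then 3.21 to 3.47), chromosome 3 at 20.8 Mb (2.25 to 2.39) and 88.2 Mb (2.65 to 3.38) and chromosome 1 at 31.3 Mb (2.57 to 2.85) also lost it when single libraries were left out, as did those on chromosome 3 at 20.8 and 88.2 Mb with library weights (log2 fold changes of 1.36 and 1.35) and the latter with a pseudocount of 0.5 interval (3.34).

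**Figure D4:**
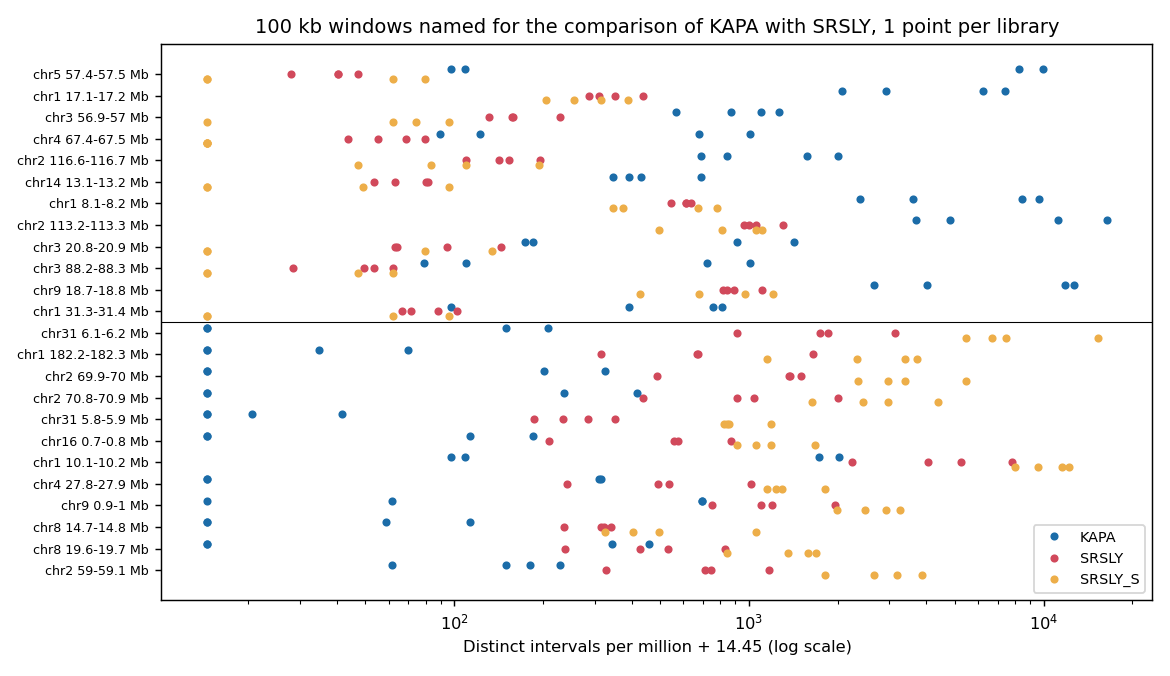
Density of distinct intervals plus 14.45 (RPM, horizontal axis, log scale) in the 24 named 100 kb windows, with 1 point per library coloured by library type. The 12 windows above the line were higher in KAPA, by a log2 fold change of 2.91 to 4.79, and the 12 below it were lower.

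Libraries of the same kit, with SRSLY and SRSLY_S pooled, also resembled each other more on average. Over 10514 windows, with all libraries thinned to 12036 intervals, the mean Spearman correlation across windows was 0.332 within a kit and 0.303 between kits, a difference of 0.0294 (exact permutation test, one-sided, p = 0.0123, the smallest it can give). Without thinning the difference was 0.0618 (exact permutation p = 0.111). It was 0.0206 (p = 0.111) and 0.0185 (p = 0.0741) in the same exact permutation test without the Tyrannosaurus osteocytes KAPA or the Tyrannosaurus vessels KAPA library. The pooled means do not hold for every pairing of library types. After thinning, SRSLY libraries correlated with SRSLY_S libraries, counted as within a kit, at 0.263 to 0.359. Correlations of KAPA with SRSLY_S libraries, counted as between kits, covered nearly the same range, 0.259 to 0.358. At the level of whole chromosomes, a unit added after the data were seen, 3 of 34 differed in limma. KAPA was higher on chromosome 10 (log2 fold change 0.68 ± 0.16, SE, 2.11% against 1.32% of intervals) and chromosome 14 (0.55 ± 0.13, 1.02% against 0.718%) and lower on chromosome 21 (-0.65 ± 0.17, 0.292% against 0.449%). The limma count was 0 without the 4 shallowest libraries (3 at an unadjusted p under 0.05), with non-repetitive intervals only (6 unadjusted), and without any 1 of 5 libraries (7 to 9 unadjusted), which were the Brachylophosaurus osteocytes KAPA, Brachylophosaurus vessels SRSLY_S, Tyrannosaurus osteocytes KAPA, Tyrannosaurus osteocytes SRSLY and Tyrannosaurus vessels KAPA libraries. It was 1 without the Tyrannosaurus vessels SRSLY_S library and 5 without the Tyrannosaurus vessels SRSLY library or with library weights. With median ratio scaling it was 6 (5 higher and 1 lower in KAPA). When every deposited interval was counted it was 21 (6 higher and 15 lower in KAPA).

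SRSLY_S libraries held more runs of C or G than the SRSLY libraries of the same sample, 40.8% ± 6.59 against 15.7% ± 7.58 (SD, n = 4 each), with 4 of 4 pairs higher by a mean of 25.04 points. Their GC content was 64.9% ± 7.66 against 43.5% ± 5.49, and low-complexity sequence made up 90.1% ± 2.60 against 74.0% ± 3.80, each higher in 4 of 4 pairs. Non-repetitive intervals of at least 50 bases made up 2.96% ± 1.72 in SRSLY_S and 13.2% ± 3.999 in SRSLY libraries, and the chromosome 16 stretch 1.17% ± 0.557 against 3.68% ± 0.665, each lower in 4 of 4 pairs. As a share of non-repetitive intervals, which was not tested, the stretch was higher in the Brachylophosaurus SRSLY_S libraries (14.4% and 16.5% against 11.4% and 12.1%). By that share it was lower in the Tyrannosaurus ones (5.24% and 9.09% against 16.8% and 17.8%). The SRSLY_S libraries were also shallower in 4 of 4 pairs, with 14.87 ± 0.82 against 18.21 ± 1.47 as log2 of the distinct intervals, and lower in 4 of 4 in repeated coordinates (19.1% against 37.5%), mitochondrial intervals (0.0148% against 0.0732%) and AACCCT repeats (0.0561% against 0.377%), while their share in the densest 1% of 10 kb windows was higher in 4 of 4 (69.0% against 40.04%). With 4 pairs, the exact permutation test (two-sided) gave p = 0.125 for each of these 10 measures, the smallest it can give, and adjusted p = 0.175, so none could pass 0.05. The mitochondrial and AACCCT shares of SRSLY_S rest on few intervals. The Tyrannosaurus osteocytes and vessels libraries held 2 and 2 mitochondrial and 2 and 0 AACCCT intervals, under the counting floor of 3. The Brachylophosaurus ones held 10 and 5 mitochondrial and 39 and 28 AACCCT intervals.

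Between SRSLY_S and SRSLY, 17 of 34 whole chromosomes passed the limma threshold, 5 higher and 12 lower in SRSLY_S, but among the 35 splits of these libraries another gave 23, and 2, the real one included, gave at least 17. Chromosome 31 held 8.78% ± 2.74 of the intervals in SRSLY_S and 2.27% ± 1.39 in SRSLY (SD, n = 4 each, log2 fold change 2.11, limma adjusted p = 0.0066). Chromosome 30 held 9.48% against 2.48% (log2 fold change 2.05, limma adjusted p = 0.00693), and chromosomes 25, 33 and 9 were higher by log2 fold changes of 1.11, 0.64 and 0.58. Chromosome 16 was lower, with 1.79% ± 0.563 against 4.15% ± 0.547 (log2 fold change -1.27, limma adjusted p = 0.0322). With non-repetitive intervals only, 2 chromosomes passed, 31 (log2 fold change 3.38) and 30 (2.98), while chromosomes 25, 33, 9 and 16 did not (0.52, 0.53, -0.001 and -0.45, limma adjusted p of 0.498, 0.498, 0.996 and 0.669). The count was 3 without each of the Brachylophosaurus vessels SRSLY_S, Tyrannosaurus osteocytes SRSLY and Tyrannosaurus vessels SRSLY libraries, each time 3 higher and 0 lower in SRSLY_S. At an unadjusted limma p under 0.05 these fits gave 19, 15 and 14, against 24 with all libraries. Without the Tyrannosaurus osteocytes SRSLY_S library the count was 7 (3 higher, 4 lower, 14 unadjusted). It was 4 when every deposited interval was counted (3 higher, 1 lower, 6 unadjusted) or with median ratio scaling (4 higher, 0 lower, 15 unadjusted). With median ratio scaling no chromosome, 16 included, was called lower. Of the 1021 windows of 100 kb, 0 passed in limma (194 at an unadjusted p under 0.05, smallest adjusted p = 0.134), against 113 with library weights, 45 without covariates and 1612 when every window with an interval was tested.

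Between the specimens, no sequence class or region passed in tests over all library types. AT repeats made up 0.287% ± 0.140 of the distinct intervals in Tyrannosaurus and 2.40% ± 3.35 in Brachylophosaurus (SD, n = 6 each). They were higher in Tyrannosaurus in 3 of 6 matched pairs (exact permutation test, two-sided, p = 0.469, adjusted p = 0.729). In the KAPA libraries they made up 6.44% and 7.01% in Brachylophosaurus and 0.180% and 0.109% in Tyrannosaurus. A specimen difference limited to KAPA had no term in these tests and was not tested. Runs of C or G made up 31.6% ± 17.4 of the distinct intervals in Tyrannosaurus and 26.3% ± 9.67 in Brachylophosaurus (SD, n = 6 each), higher in 3 of 6 pairs matched on tissue and library type (exact permutation test, two-sided, p = 0.5, adjusted p = 0.729). Runs of A or T made up 23.5% ± 9.79 and 25.1% ± 9.998 (exact permutation p = 0.562), and the chromosome 16 stretch 2.17% ± 1.78 and 2.06% ± 1.07 (exact permutation p = 0.844). Among the 14 measures the smallest exact permutation p was 0.25, for median interval length, 37.5 against 38.3 bases. In limma, 0 of 1021 windows (113 at an unadjusted p under 0.05, smallest adjusted p = 0.443) and 0 of 34 chromosomes (1 unadjusted) passed. With library weights, and with non-repetitive intervals only, 2 windows passed. The mean Spearman correlation across windows was 0.317 within a specimen and 0.319 between specimens, a difference of -0.00126 where permuted labels averaged -0.00309 (exact permutation test, one-sided, p = 0.406). Among pairs of the same library type, a restriction added after the data were seen, it was 0.369 within (6 pairs) and 0.339 between (12 pairs), with p = 0.25 in the exact permutation test, which cannot go below 0.125 there. The KAPA pairs within a specimen had 0.421 each and those between specimens 0.331 to 0.358, while the ranges overlapped for SRSLY and SRSLY_S.

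Between osteocytes and vessels, no sequence class or region passed either. Runs of C or G made up 29.7% ± 14.7 of the distinct intervals in vessels and 28.2% ± 13.9 in osteocytes (SD, n = 6 each, exact permutation test, two-sided, p = 0.75, adjusted p = 1), and runs of A or T 23.2% ± 8.01 and 25.4% ± 11.4 (exact permutation p = 0.469). The smallest p was for the AACCCT repeat, the unit of vertebrate telomeres, with 0.621% ± 0.878 in vessels and 0.119% ± 0.0713 in osteocytes (higher in 4 of 6 pairs, exact permutation p = 0.188, adjusted p = 1). In limma, 0 of 1021 windows (6 at an unadjusted p under 0.05) and 0 of 34 chromosomes (0 unadjusted) differed, and 0 windows had a tissue difference that differed between specimens (8 unadjusted). With library weights, 4 windows differed between tissues. Libraries of the same tissue had a mean correlation of 0.313, and those of different tissues 0.322 (exact permutation test, one-sided, p = 0.375), and among pairs of the same library type these were 0.335 and 0.355 (exact permutation p = 0.875). On simulated counts with independent libraries the same fits found 48% of windows changed 2-fold and 99% of those changed 4-fold between specimens. Between tissues they found 43% and 99%. The simulated spread was a set value and not estimated from the real libraries, so these rates do not tell which real differences could be detected.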

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

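The tests of sequencing direction, ribosomal primer sites, sequence variety, shared ends and copy number were fixed before their results were seen, while the 2 depth tests of shared intervals, and the counts for whole chromosomes, were chosen after. The first depth test was defined with values in view, and the second was added, with the pattern reworded, once the first had given its value. Copy numbers were later summed over both strands.

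The number of distinct intervals moved in opposite directions with the kit. On the log2 scale KAPA minus the mean of both SRSLY libraries was 2.20 in Brachylophosaurus and -2.81 in Tyrannosaurus, a difference of -5.01 that was not tested. For runs of C or G the same contrast was -9.11 points in Brachylophosaurus and 13.2 in Tyrannosaurus (difference 22.3), and for AT repeats it was 6.49 and -0.214 points (difference -6.70), both not tested. In each case both tissues of a specimen moved the same way. With 1 library per kit, specimen and tissue, chance alone gives such opposite directions in 12.5% of comparisons, which is 7 of the 56 looked at, and 3 were seen. Beyond the windows and chromosomes compared, 1442 distinct mitochondrial intervals (0 to 702 per library), whose share alone was compared, and 105280 distinct intervals on unplaced scaffolds (2.41% to 12.6% of a library) were present, with no control samples to set them against.

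The first pattern weighed was the large share of runs of C or G. In the direction of sequencing, a median of 97.2% of such intervals over 12 libraries read as G (80.1% to 99.3%), which argues against C/G homopolymer fragments read from both ends, since those would read as G and C about equally. Cycles without signal read as G, as in instruments where no colour stands for G, may account for the runs, and the same 97.2% is the value this explanation needs. Runs of A or T were one-sided too, with a median of 11.7% read as T (0.864% to 30.2%), which a missing signal read as G would not give. A preparation that keeps only 1 strand was not tested. The KAPA libraries, whose kit ligates double-stranded DNA, had 0.864% and 4.88% (Brachylophosaurus osteocytes and vessels) and 21.2% and 3.93% (Tyrannosaurus) read as T. These values argue against such a preparation for KAPA, while it stays open for SRSLY and SRSLY_S. No biological explanation was tested.

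The second pattern was the chromosome 16 stretch with the densest non-repetitive intervals. Of the intervals on assembled chromosomes with a universal 18S primer site, 97.6% lay there, as ribosomal RNA genes at this place would give. These genes are conserved, so DNA of many eukaryotes could align to them. At 20 sites of 30 bases the commonest sequence held a median of 78.5% of the intervals (45.1% to 97.2%), just below the 80% bound set beforehand for more than 1 organism, while within single libraries the median was 88.6%, above that bound, and variants among the gene copies, damage or sequencing error may lower both, so the number of organisms stays open. Sequence of the specimens themselves and contamination were not told apart by these values.

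The third pattern was that SRSLY_S libraries of both specimens shared most non-repetitive intervals of at least 40 bases with the Tyrannosaurus vessels SRSLY library, 22.0% to 30.6% of theirs, while the Brachylophosaurus ones shared 4.91% and 6.07% with the SRSLY library of their own sample. Ribosomal fragments with equal ends by chance are argued against, since outside the chromosome 16 stretch the median was still 21.5%. Depth was tested by thinning the SRSLY libraries in 2 ways. With all intervals thinned alike, the mean share of the 3 SRSLY_S libraries of other samples was 1.44 times that with their own library. For the Tyrannosaurus against the Brachylophosaurus SRSLY libraries the ratios were 2.885 and 1.58 in the Brachylophosaurus SRSLY_S libraries and 11.01 and 12.07 in the Tyrannosaurus ones. These excesses thus stayed after this thinning, but the lead of the Tyrannosaurus vessels SRSLY library over the Tyrannosaurus osteocytes one did not stay throughout. The Brachylophosaurus osteocytes and vessels SRSLY_S libraries then shared 7.76% and 10.4% with the vessels library. They shared more, 8.62% and 11.05%, with the osteocytes library. The Tyrannosaurus osteocytes and vessels SRSLY_S libraries shared 15.2% and 10.8% with the vessels library and 14.0% and 10.4% with the osteocytes one. With the non-repetitive intervals of at least 40 bases thinned to the same number, the first ratio was 0.496 (yet 1.65% against 0.877% for Brachylophosaurus osteocytes). The others were then 1.465, 0.732, 4.181 and 4.686. This way ignores copies and lowers each share about in proportion to the intervals removed, so it cannot decide on depth. Depth as a part of the excess stays open. Shared intervals had a median of 33.6 times as many copies in the Tyrannosaurus vessels SRSLY library as others. Carry-over of its molecules or reads would give this, but any sampling of abundant sequence could give it too. Both specimens going through common reagents was not tested.

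For the 261 windows that differed between kits, 1 of 100 splits of the libraries, the real one, gave as many. The highest count among the other splits was 31. This way of drawing splits replaced a first scheme after that scheme had been seen. The first scheme took 4 libraries as KAPA without a term for the suffix, and the real grouping fitted that way gave 218 windows. Another split gave 377, and 2 of 100, the real one included, were as large as either 261 or 218. Since the second scheme was chosen with the first in view, chance is not called excluded for these windows. For the 3 chromosomes between kits, 2 of 100 splits gave as many, and another split gave 12. The unit was chosen after the data were seen and the calls were lost without any 1 of 5 libraries, so these splits are not read as excluding chance for them. Chance could not be excluded for the 17 chromosomes between SRSLY and SRSLY_S, where 2 of 35 splits gave as many and another gave 23. These splits were not limited to those that keep the SRSLY and SRSLY_S library of a sample apart, so they ignore the pairing. A count of 0 is reached by every split by construction (100 of 100, and 35 of 35 for SRSLY and SRSLY_S), so the splits decide nothing there, and the highest others were 270 windows and 14 chromosomes for specimens, 28 and 11 for tissues, 98 windows for SRSLY and SRSLY_S, and 28 windows for the interaction. The split with 270 windows, where the real one had 0, points to some structure of the libraries, which was not tested.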

How the results depend on the processing

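The settings limited to non-repetitive intervals or to pairs of the same library type, without the 4 shallowest libraries and all settings for whole chromosomes were chosen after the data were seen, the others before. Among the values that answer a comparison, 225 alternatives kept the direction and side of the threshold, 13 moved past it or to over 1.5 times the count, and 24 fell back. For single regions and measures these were 1842, 4 and 32, with 7 values moved by more than 1 SD and 2 reversed. A filter on a mapping score of 30, exon counts, annotated genes in place of windows and gene lists were not run, since the score is 0 throughout and no annotation was used here. In the counts below, fewer windows were tested with non-repetitive intervals only (71 of 1021) and fewer libraries without the 4 shallowest, and for the rest the cause was not tested.

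With every deposited interval, 483 windows and 21 chromosomes (6 higher and 15 lower in KAPA) differed between kits. Under the same setting 4 chromosomes differed between SRSLY and SRSLY_S (3 higher and 1 lower in SRSLY_S), and the KAPA excess of runs of A or T turned to -0.962 points. With every window that held an interval, 149 windows differed between kits and 1612 between SRSLY and SRSLY_S (1584 lower in SRSLY_S). With library weights, 2 windows differed between specimens, 4 between tissues and 113 between SRSLY and SRSLY_S, and 5 chromosomes between kits. Without covariates, 45 windows differed between SRSLY and SRSLY_S. With median ratio scaling, 6 chromosomes differed between kits (5 higher and 1 lower in KAPA) and 4 between SRSLY and SRSLY_S (4 higher and 0 lower in SRSLY_S). With non-repetitive intervals only, 2 windows differed between specimens, 34 between kits and 10 between SRSLY and SRSLY_S, with 0 chromosomes between kits (limma, 6 at an unadjusted p under 0.05) and 2 between SRSLY and SRSLY_S. Without the 4 shallowest libraries, 47 windows and 0 chromosomes (limma, 3 at an unadjusted p under 0.05) differed between kits. Without thinning, the similarity by kit was 0.0618. Without the densest 1% of windows, the rest of the chromosome 16 stretch was 0.0127 points higher in KAPA, against -0.941 points for the whole stretch. This setting takes away the dense windows that make up the stretch, so it says nothing on the difference itself.

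Leaving out 1 library at a time gave 100 to 301 windows and 0 to 5 chromosomes between kits, 0 to 1 windows and 3 to 25 chromosomes between SRSLY and SRSLY_S, and similarities by kit of 0.0185 to 0.0351. The lowest window counts came without the Tyrannosaurus KAPA libraries (100 for vessels, 140 for osteocytes) and the Tyrannosaurus osteocytes SRSLY library (149), and 1 SRSLY and SRSLY_S window appeared without the Brachylophosaurus osteocytes SRSLY_S library. Depth limits the 4 libraries with under 25000 distinct intervals most, since a window at the minimum density holds few of their intervals.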

Other observations

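All values in this part were computed after the data were seen, and they are given without explanation. The thinning and the count of coordinates for AT repeats were set up as tests of depth and of copying, and were then kept as values only.

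AT repeats stood apart in the KAPA libraries of Brachylophosaurus. They made up 6.44% of the distinct intervals of the osteocytes library and 7.01% of the vessels library, and at most 0.481% in each of the other 10. With every library thinned to 20044 deposited intervals, copies included, AT repeats made up 32.0% and 42.2% in these libraries and at most 0.284% elsewhere, a ratio of 112 between the lower of the pair and the highest other. They lay at 27045 coordinates, and the 10 commonest held 8.69% of the 927943 deposited AT intervals. Without a mapping quality, placement among AT repeats could not be checked. These counts therefore do not tell how many molecules gave the signal. The window on chromosome 5 from 57.4 to 57.5 Mb was led by this class.

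Of the non-repetitive intervals of at least 40 bases in the smaller library of a pair, KAPA libraries shared 0% to 3.90% with SRSLY or SRSLY_S libraries (32 pairs) and also 0% to 3.90% with each other (6 pairs). The SRSLY and SRSLY_S libraries shared 1.19% to 30.6% with each other (28 pairs). The pairs differ in depth and were not tested.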
